A study of Mus musculus with 20 samples.

How the data were processed

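Total RNA of CD45.1+ OT-I CD8+ T cells from 4 sites was amplified, labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, 20 arrays in all, per the labels' protocols. Groups were the 4 sites named in the labels, with 5 arrays each, and replicate numbers were those of the titles. Each array file holds 44397 spots, of which 1377 were controls. The remaining 43020 spots covered 39429 probes. Signal intensity was extracted from the scans with Feature Extraction 11.0.1.1, per the file headers, whereas the submitters' processing notes name version 10.7 and Partek. The processed signal is a background-subtracted intensity on a linear scale, per the file headers, and the flags for non-uniform, saturated and well above background spots were taken as the deposited files give them. The authors' deposited value table is on a log2 scale. It equals quantile-normalized log2 processed signal with a median absolute difference of 3.47e-06, each column has a median of 8.05, and it was used as an alternative.

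From the intensity, log2 processed signal was taken and the 75th percentile of each array was subtracted. Control spots and 24 non-uniform spots were left out, and 1 spot was saturated. Spots of a probe were averaged. Probes were named through unversioned RefSeq accessions with a gene table of assembly GRCm38.p6, which gave 27508 probes 1 symbol, over 20886 genes, and left 11921 without a symbol, which were not analysed here by gene. No coordinates are given, since the array design uses another build. For 5512 genes with several probes the brightest on average was used. A gene was tested where its probe was well above background on at least 4 of 5 arrays of at least 1 site. This kept 8057 genes, and only these are called measured below. A marker of other cells that passes only through the site where it is bright is higher there by selection. Shares and camera results of marker lists therefore lean towards that site. Where a probe was not well above background on any array of a site, the difference is given as a lower bound, "at least N-fold", from the bright site's mean and, per array of the dim site, the higher of the lowest signal among probes well above background and the probe's own signal.

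Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with 1 coefficient per site over all 20 arrays and 16 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjustment within each of 6 contrasts at a threshold of 0.05. An F-test covered the 4 sites. Gene lists (22 about T cells, 20 of markers of other cells) were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it, with 38 lists holding at least 3 tested genes. The lists, the tests, the rule for named genes and the first alternatives were fixed before the data were examined. Of 789 list members 756 had a probe. Named were, per contrast, the 6 largest increases and 6 largest decreases among genes with adjusted p under 0.05, a log2 size of at least 1 and no overlap between the 5 and 5 values (names that are not symbols left out). Up to 4 called members of each T cell list, up to 3 members of each other-cell list and a fixed set of T cell genes were also named, and up to 6 genes for those set apart in 1 site. A gene among these is not reported here.

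Each slide held 1 array of every site and all arrays with the same replicate number, so the slide block and the replicate block are the same model, and within a slide there is 1 difference per gene, counted as slides with the same direction. Between 22.6% and 38.7% of the probes were well above background on an array, so scaling on the 6836 probes well above background on all 20 arrays was added after the data were seen. The median log2 difference over all genes was 0.05 for liver, -0.30 for lung and -0.36 for small intestine against blood, -0.25 for lung and -0.34 for small intestine against liver, and -0.15 for small intestine against lung, and it was -0.13, -0.48, -0.32, -0.25, -0.12 and 0.08 with that scaling. List medians are therefore also given relative to it. Other alternatives were quantile normalization, median scaling, other filters, a block, pairwise fits, the mean of a gene's probes, kept non-uniform spots, another variance model, the deposited value table and each array left out in turn. The procedure was tested on simulated data with 200 changed genes per comparison among 8056. Genes were simulated as independent, each with the same spread at all sites and with no array standing apart. The real arrays do not meet this, so the shares recovered hold for that setting only. Of 50 genes changed by 2 on the log2 scale it recovered 72% for liver against blood, 80% for lung against blood, 86% for small intestine against blood, 86% for lung against liver, 82% for small intestine against liver and 86% for small intestine against lung. Of 50 changed by 1 it recovered 20%, 14%, 22%, 32%, 22% and 26%. Figures were drawn with matplotlib 3.10.9.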

Results

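Gene expression was measured in donor CD8+ effector T cells taken from the liver, the lung, the small intestine and the peripheral blood of mice with lethal acute graft-versus-host disease. The donor cells carried the OT-I receptor, which recognises an ovalbumin peptide, and the recipients carried an ovalbumin transgene. Recipients received 11 Gy of irradiation and a graft of bone marrow cells and splenocytes, and the cells were recovered on day 4 by magnetic sorting for the donor marker CD45.1. There were 5 arrays for each of the 4 sites, 20 in all. Each of 5 slides held 1 array of every site. The signal at the 75th percentile ran from 823 to 2848 per array, and between 22.6% and 38.7% of the probes lay well above background. The labels tie no array to an animal, so p-values measure the spread between these arrays, and the number of arrays limits the precision. The comparisons address how effector T cells in the target organs of the disease differ from one another and from those in blood. All values below are log2 signals relative to the 75th percentile of the array, with differences given with their standard error (SE) from limma.

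The 15 measured genes of the CD8 T cell identity list, which holds the T cell receptor complex and its signalling proteins, averaged 5.08 ± 0.20 (SD, n = 5) in blood, 5.22 ± 0.14 in liver, 4.86 ± 0.26 in lung and 4.48 ± 0.84 in small intestine. None of the 15 passed the threshold in any organ against blood (limma), and as a list they did not pass camera there either (adjusted p = 0.227 in liver, 0.881 in lung and 0.130 in small intestine). Small intestine 1, 2 and 4 nevertheless averaged 4.40, 3.75 and 3.57, each below the lowest blood array (4.81). Small intestine 3 and 5 averaged 5.44 and 5.22. Lung 2 and lung 4, at 4.77 and 4.48, also lay below the lowest blood array, while lung 1, 3 and 5 averaged 4.87, 5.13 and 5.05. Markers of other cells differed between sites. Alveolar macrophage markers averaged 2.66 ± 2.89 in lung against -2.41 ± 0.72 in blood, and Paneth cell markers averaged 3.83 ± 4.29 in small intestine against -1.92 ± 0.76 in blood. The array labelled lung 3 averaged -2.18 for alveolar macrophage markers. The array labelled liver 5 averaged 4.48 for Paneth cell markers, and the array labelled small intestine 5 averaged -3.06. Comparisons are therefore also given without the arrays labelled liver 5 and small intestine 5, an alternative chosen after the data were seen.

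**Figure D1:**
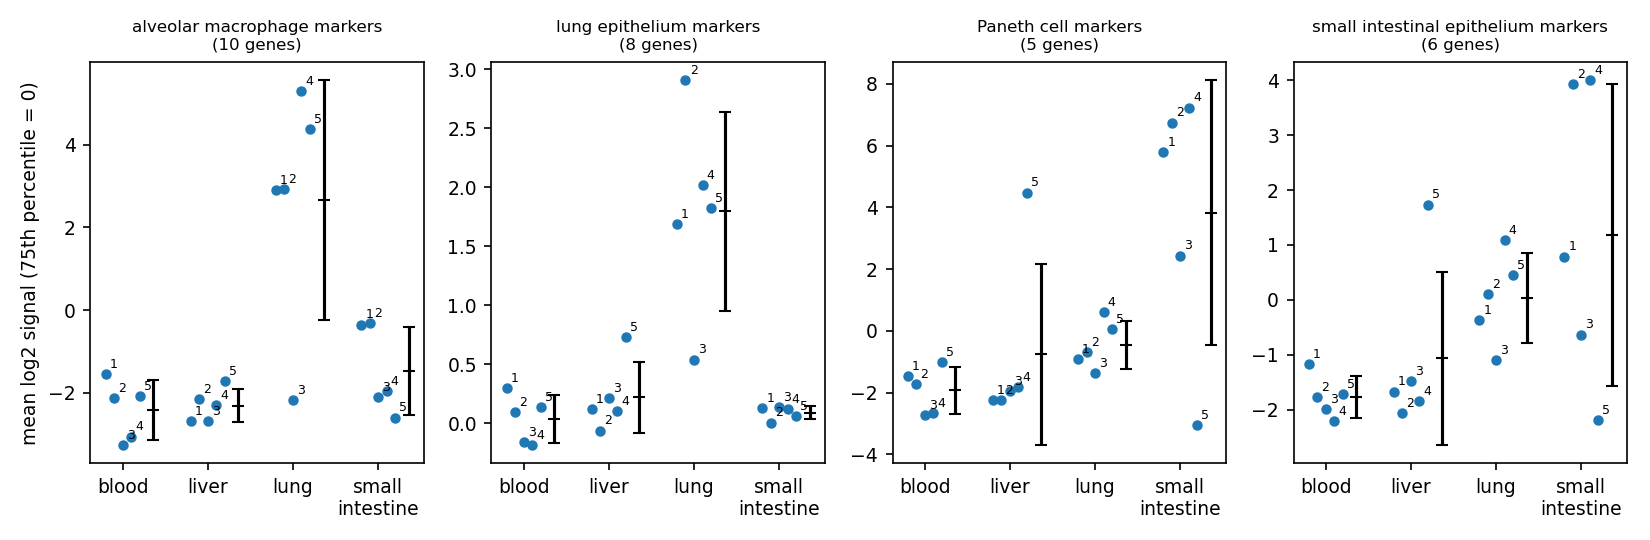
Mean log2 signal of 4 marker lists on each array (points, numbered by replicate), with the mean and SD of each site of 5 arrays (bars). The array labelled liver 5 lies at 4.48 for Paneth cell markers, and the array labelled small intestine 5 lies at -3.06.

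No gene passed the threshold between liver and blood (0 of 8057 genes with limma, 225 at an unadjusted p under 0.05), while 5 gene lists passed camera, of which 1 also passed with an estimated correlation. The immediate early list, of genes induced early after antigen receptor signalling, was higher in liver. What raised it, in this organ or in the others, was not tested. Its median log2 difference was 0.97 over 20 genes, 0.92 above the median of all genes (camera adjusted p = 1.4e-13, 0.013 with an estimated correlation, higher on 5 of 5 slides). Adjusted over the list alone, 4 of the 20 were higher, and none when adjusted over all genes. The tissue residency program is a list of genes known to be higher in T cells that stay in tissue. It shares Cd69, Nr4a1, Nr4a2, Egr1, Atf3 and Junb with the immediate early list, so results on these lists are not independent. The tissue residency program had a median difference of 0.43 (camera adjusted p = 0.00093, but adjusted p = 0.44 with an estimated correlation, higher on 3 of 5 slides). Without the arrays labelled liver 5 and small intestine 5 its median was 0.22 (camera adjusted p = 0.043), that of the immediate early list 0.76 (camera adjusted p = 7.3e-14) and that of costimulatory receptors and ligands 0.21, which no longer passed (camera adjusted p = 0.19). Neutrophil markers were higher by a median of 1.84 over 5 genes (camera adjusted p = 0.0073, adjusted p = 0.22 with an estimated correlation). Lists of costimulatory receptors and ligands (median 0.38, camera adjusted p = 0.030) and of fatty acid and cholesterol metabolism (median -0.10, camera adjusted p = 0.033) also passed camera, each with adjusted p = 0.44 and adjusted p = 0.22 with an estimated correlation, respectively. Ccr7, a receptor that guides T cells to lymph nodes, differed by 1.58 ± 0.53 and Cd69, an early activation and retention receptor, by 1.53 ± 0.70, both with adjusted p = 0.997 in limma. Perforin (Prf1) differed by -1.11 ± 0.56 and granzyme B (Gzmb) by -0.40 ± 0.56, which did not pass either. With the slide as a block 3 genes passed, namely Cd83, Cxcl10 and Dusp1, which were named after their values were seen and were higher in liver on 5 of 5 slides. Leaving out the array labelled liver 3 gave 2 genes, and testing dim probes too gave 2.

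Lung and blood differed in 66 genes, 42 higher and 24 lower in lung. Genes of lung-resident cells rose. Chil3, a secreted protein of alveolar macrophages, was higher by 7.75 ± 1.62 (adjusted p = 0.026, limma). Ear2 and Ear1, ribonucleases of the eosinophil-associated family, were at least 47.5-fold and at least 18.9-fold higher (adjusted p = 0.0089 and 0.0053), since their probes were not well above background on any blood array. The surfactant genes Sftpc and Sftpd were at least 36.3-fold and at least 8.40-fold higher, and Sftpa1 at least 2.47-fold. These 3 genes, like Ear1 and Ear2, were well above background on 4 of the 5 lung arrays. Over the list, 6 of 10 measured alveolar macrophage markers rose, with a median difference of 4.87 (camera adjusted p = 7.4e-12, but adjusted p = 0.11 with an estimated correlation), and 3 of 8 lung epithelium markers rose (median 0.88, camera adjusted p = 0.00047, adjusted p = 0.11 with an estimated correlation). Adjusted over the list alone, 9 of the 10 alveolar macrophage markers and 3 of the 8 lung epithelium markers were higher. Of the markers with a probe, 10 of 11 alveolar macrophage, 8 of 16 lung epithelium and 7 of 20 endothelial ones were measured. The nuclear receptor Pparg, which is known for lipid metabolism, was at least 2.25-fold higher (adjusted p = 0.044). Fabp1, a fatty acid binding protein of liver and gut, was at least 5.44-fold higher (adjusted p = 0.017). The endothelial receptor Flt1 was higher by 2.62 ± 0.59 (adjusted p = 0.043), and endothelial markers as a list rose by a median of 1.07 over 7 genes (camera adjusted p = 0.00033, adjusted p = 0.11 with an estimated correlation).

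Of the 20 immediate early genes measured, 3 were higher in lung at the threshold over all genes and 9 adjusted over the list alone, with none lower. Fos rose by 4.40 ± 0.87, Dusp1, a phosphatase that limits MAP kinase signalling, by 2.10 ± 0.41 and Jun by 1.63 ± 0.35 (adjusted p = 0.020, 0.018 and 0.030). The list passed camera (adjusted p = 1.5e-06) but not with an estimated correlation (adjusted p = 0.11). Fos lay between -3.71 and -2.16 on the blood arrays 3, 4 and 5, and at 1.27 and 1.48 on blood arrays 1 and 2. Anxa1, an anti-inflammatory lipid-binding protein, rose by 3.51 ± 0.71, Lmna, a nuclear lamina protein, by 3.23 ± 0.73, and Sema3f by at least 4.61-fold. The genes that fell included Haspin, a mitotic kinase (at least 2.23-fold lower), Stil, which is needed for centriole duplication (at least 1.30-fold lower), Zkscan5 (-2.50 ± 0.39), Dhx33 (-2.25 ± 0.52), Klhl12 (-2.07 ± 0.46) and Zfp687 (-2.04 ± 0.47). None of the 30 cell cycle genes passed on its own, while as a list their median was -0.61, 0.31 below that of all genes (camera adjusted p = 0.0073, adjusted p = 0.62 with an estimated correlation). Glycolysis genes had a median of -0.69 over 19 genes (camera adjusted p = 0.025, adjusted p = 0.54 with an estimated correlation). Cytotoxic effector molecules held no call among 11 genes, with Prf1 at -1.67 ± 0.56 and Gzmb at -1.11 ± 0.56 (adjusted p = 0.12 and 0.16). CD8 T cell identity means were below every blood array on lung 2 and lung 4, so a lower share of T cells stays open for the falls in lung. The count was 114 with the slide as a block, 31 under quantile normalization, and 175 (80 higher and 95 lower) without the arrays labelled liver 5 and small intestine 5. Both that omission and scaling on the probes well above background on all 20 arrays gave 83 genes differing between lung and blood that were higher and 448 lower, against 42 and 24. Normexp on median signals gave 25 and 24. No gene passed when only the probes well above background on all 20 arrays were tested. Scaled on those probes alone the count was 24, all among the 66, and of the genes named here these held Sftpc, Sftpd, Sftpa1, Ear1, Ear2, Fabp1, Stil, Zkscan5 and Haspin, but not Fos, Dusp1 or Jun. Leaving out 1 array gave between 16 (blood 3) and 846 (lung 1), with 105 without lung 3, 23 without lung 4, 18 without lung 5, and 31, 25 and 24 without blood 2, blood 4 and blood 5.

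The small intestine differed from blood in 873 genes, of which 74 were higher and 799 lower in the small intestine. The Paneth cell defensins Defa3 and Defa23 were higher by 5.67 ± 1.38 and 5.52 ± 1.46 (adjusted p = 0.021 and 0.027), and Defa29 was at least 21.9-fold higher, on 4 of 5 slides. Jchain, which joins secreted immunoglobulin chains in plasma cells, was at least 14.1-fold higher, also on 4 of 5 slides. Lgals4, a lectin of gut epithelium, rose by 4.01 ± 1.09 and Cd74, the class II invariant chain, by 4.13 ± 1.22. Of 10 Paneth cell markers with a probe 5 were measured, and of 29 small intestinal epithelium markers with a probe 6. Of the 5 measured Paneth cell markers 4 rose, with a list median of 5.67 (camera adjusted p = 8.6e-06, adjusted p = 0.20 with an estimated correlation). Small intestinal epithelium markers had 1 of 6 higher (camera adjusted p = 0.00017, adjusted p = 0.20 with an estimated correlation) and dendritic cell markers 2 of 8 (camera adjusted p = 0.0007, adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, 5 of 5, 5 of 6 and 5 of 8 were higher in these lists.

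Cxcl10, an interferon-induced chemokine, rose by 4.11 ± 0.79 (adjusted p = 0.016), Cd83, an activation marker, by 4.16 ± 0.73 (adjusted p = 0.013), and Il17a, the cytokine interleukin 17A, by 3.48 ± 0.93 (adjusted p = 0.028), each on 5 of 5 slides. Il17a is also in the lists of CD4 and of gamma delta T cell markers, and monocyte and macrophage markers averaged 2.66 ± 2.36 (SD, n = 5) against 0.78 ± 0.31 in blood, so the source cell of these transcripts was not determined. Cish, an inhibitor of cytokine signalling, rose by 3.16 ± 0.94, Tnfsf11, the ligand RANKL, by 2.21 ± 0.65, and Cd274, the inhibitory ligand PD-L1, by 0.81 ± 0.25. Ramp3 rose by 4.29 ± 1.14 and the gap junction gene Gjb2 by at least 3.20-fold. Fos, Dusp1 and Jun rose by 3.46 ± 0.87, 1.81 ± 0.41 and 1.32 ± 0.35, while Irf4, a transcription factor of activated lymphocytes, fell by 2.31 (SE 0.67). Over the immediate early list 3 genes rose and 1 fell of 20, or 6 and 2 adjusted over the list alone (camera adjusted p = 4.2e-07, adjusted p = 0.20 with an estimated correlation). The tissue residency program had no single gene past the threshold among 22 and a median of 0.60, which was 0.96 above that of all genes (camera adjusted p = 0.00026, adjusted p = 0.26 with an estimated correlation).

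Of the circulating cell program, S1pr1, the receptor that draws T cells out of tissue into blood and lymph, was lower by -2.68 ± 0.71 and Arhgef18 by -1.88 ± 0.44 (adjusted p = 0.027 and 0.019), whereas Ccr7 of the same list, which is also among the dendritic cell markers, was higher by 1.84 ± 0.53 (adjusted p = 0.035). Of the 19 genes of the circulating cell program 5 fell and 1 rose, or 12 and 1 adjusted over the list alone (median -1.14, camera adjusted p = 0.023, adjusted p = 0.55 with an estimated correlation). The homing genes Itga4, an integrin chain that pairs with the gut integrin chain Itgb7, and Fut7, a fucosyltransferase, fell by 1.75 (SE 0.41) and 2.05 (SE 0.35). Itgb7 itself was at -0.36 ± 0.29 (adjusted p = 0.33) and the gut-homing receptor Ccr9 at 1.22 ± 0.85 (adjusted p = 0.28). Of 30 cell cycle genes 19 fell and none rose, 25 adjusted over the list alone, with a median of -1.29, or 0.93 below that of all genes (camera adjusted p = 1.6e-07, adjusted p = 0.26 with an estimated correlation, lower on 5 of 5 slides). Foxm1, a transcription factor of mitotic genes, fell by 2.93 (SE 0.79), Ccnb1, a mitotic cyclin, by 2.32 (SE 0.48), Mcm2, a replication helicase subunit, by 1.84 (SE 0.56) and Prc1 by 1.82 (SE 0.50), while the proliferation antigen Mki67 was at -0.38 ± 0.92 (adjusted p = 0.74), lower on 4 of 5 slides and higher on that of small intestine 5. Other decreases were in Sh2d3c (-3.58 ± 0.58), Cdca2 (-3.45 ± 0.63), Fam78a (-3.25 ± 0.62), Haspin (-2.91 ± 0.49) and Ccdc92 (-2.91 ± 0.61). Of 11 cytotoxic effector molecules Prf1 alone passed, lower by -2.05 ± 0.56 (adjusted p = 0.030). Gzma was at -0.06 ± 0.27 and Gzmb at -1.06 ± 0.56 (adjusted p = 0.86 and 0.19). Il18r1, a receptor chain for interleukin 18, was lower by -2.22 ± 0.64 and Ccr10 by -2.55 ± 0.78. Over all 8057 genes the median difference was -0.36. CD8 T cell identity means were below every blood array on small intestine 1, 2 and 4, so a lower share of T cells stays open for these falls. The size of the result rested on the scaling and on single arrays. Scaled on the probes well above background on all 20 arrays, 19 genes passed, 4 higher and 15 lower, and all 19 were among the 873. Of the genes named here these included Cd83, Cxcl10, Gjb2, Haspin, Fam78a, Sh2d3c and Fut7. Without the array labelled small intestine 2 no gene passed with limma (0, with 1934 at an unadjusted p under 0.05), whereas without small intestine 5 the count was 2037 and without small intestine 3 it was 1914. It was 368 without small intestine 1, 261 without small intestine 4, and 240, 266, 492 and 164 without blood 2, 3, 4 and 5. Without the arrays labelled liver 5 and small intestine 5, 2119 genes passed, 380 higher and 1739 lower. With both changes there were 387 higher and 1532 lower genes differing between small intestine and blood.

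**Figure D2:**
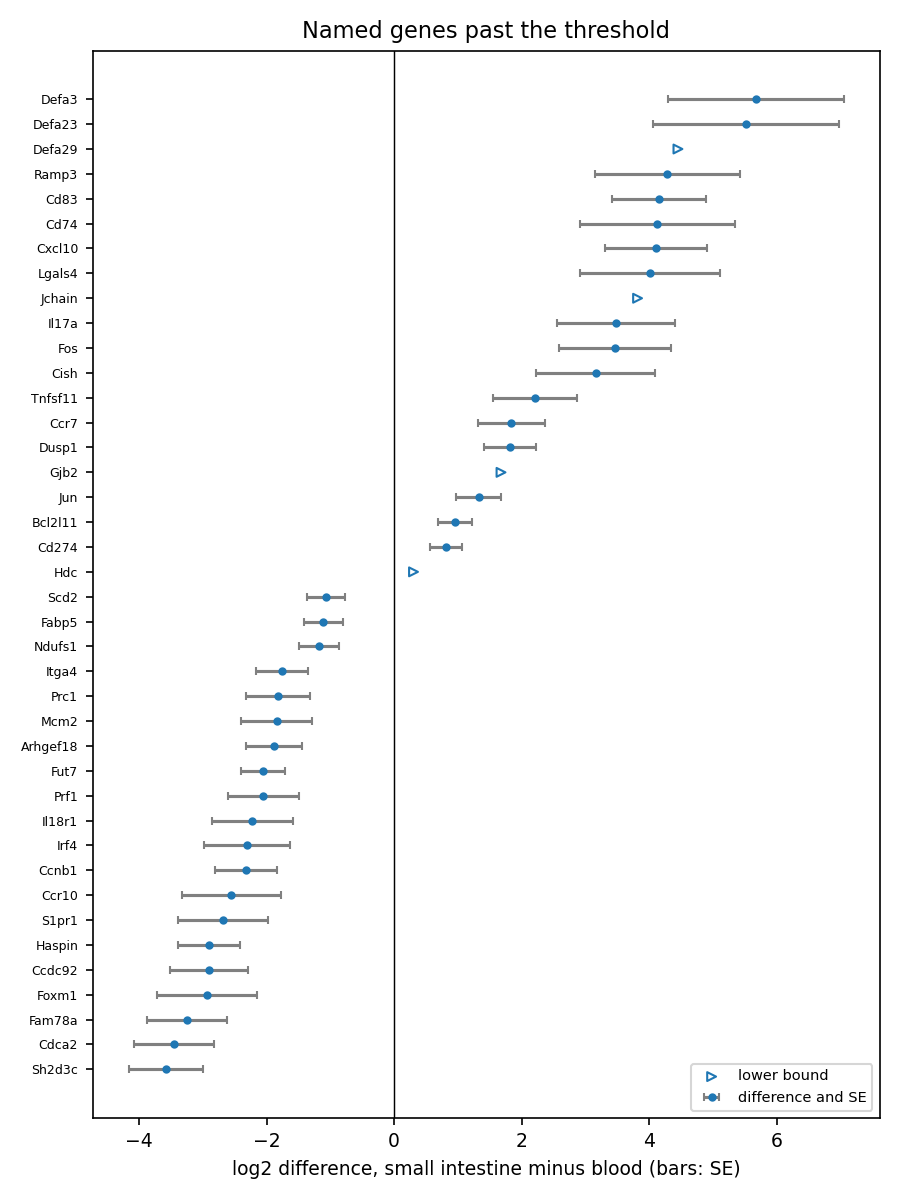
Log2 difference between small intestine and blood for the named genes past the threshold (points, limma; bars, SE; 5 arrays per site). Triangles are lower bounds, used where no blood array had the probe well above background. Values other than bounds run from -3.58 for Sh2d3c to 5.67 for Defa3.

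**Figure D3:**
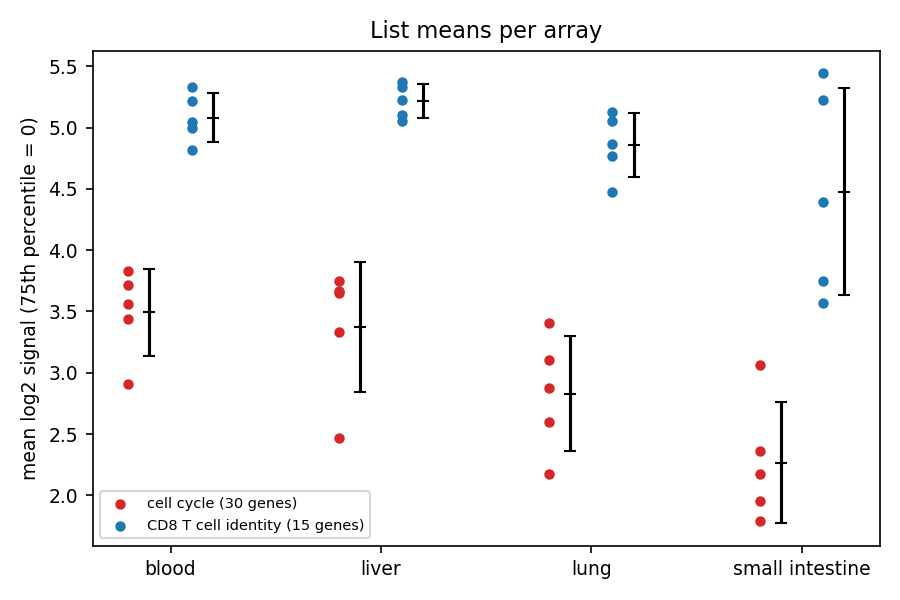
Mean log2 signal of the cell cycle list (30 genes) and of the CD8 T cell identity list (15 genes) on each array (points), with the mean and SD of each site of 5 arrays (bars). Cell cycle means averaged 3.49 in blood and 2.27 in small intestine, and identity means 5.08 and 4.48.

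Lung and liver differed in 23 genes, 20 higher and 3 lower in lung. Ear2, Ear10, Ear1 and Rnase2a, ribonuclease genes of 1 family, were at least 48.9-fold, 30.2-fold, 19.4-fold and 19.2-fold higher, the keratin Krt79 at least 16.9-fold and Sftpc at least 37.4-fold (adjusted p between 0.0064 and 0.011, limma). Flt1 was higher by 3.18 ± 0.59 and Sftpd by 3.22 ± 0.60. Alveolar macrophage markers had a median difference of 4.72 with 4 of 10 higher (9 adjusted over the list alone), lung epithelium markers 0.64 with 3 of 8 higher (3, and 1 lower) and endothelial markers 0.96 with 1 of 7 higher (4). These 3 lists passed camera and also passed with an estimated correlation (adjusted p = 0.046, 0.046 and 0.048). The 3 lower genes were Zkscan5 (-1.93 ± 0.39), Ubfd1, a ubiquitin-binding protein (-1.36 ± 0.28), and Mrpl19, a protein of the mitochondrial ribosome (at least 1.08-fold lower). No gene of a T cell list passed. The count was 32 with the slide as a block, 16 (16 higher and 0 lower) when scaled on the probes well above background on all 20 arrays, 13 (13 and 0) with median scaling, and 0 with only the 2 sites in the model (limma, 1541 at an unadjusted p under 0.05). No gene passed either with normexp on median signals or when only probes well above background on all 20 arrays were tested. Leaving out 1 array gave between 10 (lung 4) and 65 (lung 3), with 11, 13 and 14 without liver 1, 2 and 5 and 35 and 13 without lung 1 and lung 5.

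Small intestine and liver showed no gene past the threshold in limma (1776 at an unadjusted p under 0.05), in a comparison that held both arrays that stood apart. Without the arrays labelled liver 5 and small intestine 5, 1312 genes passed, 138 higher and 1174 lower in small intestine. With all arrays, all 30 cell cycle genes had a lower mean in small intestine (median -1.09, camera adjusted p = 8.5e-10, adjusted p = 0.27 with an estimated correlation), as did 18 of 19 genes of the circulating cell program (median -1.06, camera adjusted p = 0.00087, adjusted p = 0.37 with an estimated correlation). CD8 T cell identity genes had a median of -0.72, 0.38 below that of all genes (camera adjusted p = 0.0044, adjusted p = 0.44 with an estimated correlation). Paneth cell markers were higher by a median of 4.44 (camera adjusted p = 1.2e-07, adjusted p = 0.24 with an estimated correlation). Itga4 differed by -1.27 ± 0.41, S1pr1 by -1.61 ± 0.71 and Ccr9 by 1.83 ± 0.85, with adjusted p of 0.14, 0.20 and 0.22. These 3 genes passed without the 2 arrays. Leaving out small intestine 5 alone gave 822 genes and leaving out liver 5 alone gave 323.

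Small intestine and lung differed in 12 genes, 1 higher and 11 lower in small intestine. Ckb, the brain-type creatine kinase, rose by 1.59 ± 0.31 (adjusted p = 0.035, limma). Fut7 fell by 1.77 (SE 0.35, adjusted p = 0.038), the only gene of a T cell list to pass. The alveolar macrophage markers Ear1 and Krt79 and the surfactant gene Sftpc were at least 17.0-fold, 14.8-fold and 29.7-fold lower in small intestine, Atp6v0d2, a proton pump subunit, at least 5.46-fold, the lipid droplet gene Cidec at least 2.62-fold and the formyl peptide receptor Fpr2 at least 2.59-fold. The tissue residency program had a median difference of 0.49, 0.64 above that of all genes (camera adjusted p = 1.7e-05, adjusted p = 0.31 with an estimated correlation), and cell cycle genes of -0.56 (camera adjusted p = 5.2e-06, adjusted p = 0.47 with an estimated correlation). The split rested on the scaling: 12 genes were higher and 8 lower when arrays were scaled on the probes well above background on all 20, and 10 and 18 under quantile normalization, against 1 and 11. The count was 9 with the slide as a block, where Ckb, Fut7 and Fpr2 no longer passed (adjusted p = 0.055, 0.076 and 0.065), 0 with only the 2 sites in the model (limma, 451 at an unadjusted p under 0.05) and 212 (57 higher and 155 lower) without the arrays labelled liver 5 and small intestine 5. With that omission and the scaling on probes well above background 48 were higher and 63 lower. With all arrays, no gene passed with normexp on median signals or when only probes well above background on all 20 arrays were tested. Leaving out 1 array gave between 3 (lung 5) and 118 (small intestine 5), with 44 and 7 without lung 3 and lung 4 and 7, 6 and 20 without small intestine 1, 3 and 4.

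Across the 4 sites 61 genes differed in the F-test, and between 13 (without lung 5) and 1065 (without small intestine 5) when 1 array was left out; only leaving out liver 3, lung 4 or small intestine 4 kept it within 1.5 times. Genes set apart in 1 site were found in lung, where 10 genes were higher than in each of the other 3 sites. These included Ear1, Krt79, Sftpc, Atp6v0d2, Fpr2 and Cidec. Their number was 3 without lung 5, 5 without small intestine 3, 6 without liver 1, lung 4 or small intestine 1, and 32 without lung 3. None was set apart in lung with normexp, with only the sites compared in each model, or with only probes well above background on all arrays. Liver, small intestine and blood had 0 such genes in limma. In small intestine 20 were found without small intestine 5 and 7 without liver 5, in blood 1 without liver 3, and 30 were set apart in small intestine without the arrays labelled liver 5 and small intestine 5, including Defa42, Defa40, Itln1, Defa29, Jchain and Defa39. No gene was higher or lower in all 3 organs than in blood, and with the slide as a block Cxcl10 and Dusp1, named after their values were seen, were higher in all 3. Lung and small intestine shared 5 higher and 14 lower genes against blood, where independent lists of these sizes would share 0.39 and 2.38. Unchanged organs set against the same blood arrays shared 0. With the blood arrays split between the organs, the mean overlap was 0 in both directions. An overlap needs called genes, which unchanged organs hardly give and fits with fewer blood arrays give less readily. Neither 0 can therefore be set against the 5 and 14, and the part of the shared blood arrays in this overlap stays open. The log2 differences of lung and small intestine had a covariance of 0.57 (correlation 0.76 across genes, which are not independent replicates). It was 0.10 (correlation 0.49) for unchanged organs and 0.51 (correlation 0.64) with the blood arrays split. For liver and lung the covariance was 0.19 (correlation 0.55) against 0.11 (correlation 0.52) for unchanged organs and 0.13 (correlation 0.31) with the blood arrays split. For liver and small intestine the covariance was 0.24 (correlation 0.68) against 0.10 (correlation 0.48) for unchanged organs and 0.18 (correlation 0.42) with the split.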

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

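The tests of scaling and of the share of T cells were chosen only after the result was seen, and the test of the arrays labelled liver 5 and small intestine 5 after the counts without them were known, though before their positions were; the marker ratio without lung 3 and the exchange of standard errors were added last.

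Over 164 sets of 5 arrays (a gene list or a measure of array signal, in a site), 10 had an array whose gap to its nearest neighbour exceeded 0.71 of the range. Chance gives about 8.2 over all 164 sets, and all 10 were gene lists. Of these 10, 6 were the array labelled liver 5. It was the highest of the liver arrays for Paneth cell markers (gap 0.9344 of the range, 4.48 against -2.25 to -1.81), small intestinal epithelium markers (0.8448), transcription factors of effector and memory cells (0.7806), retinoic acid and TGF-beta response genes (0.7465) and costimulatory receptors and ligands (0.7216), and the lowest for adhesion and homing molecules (0.7257). The other 4 were spread over the sites. Liver 4 was highest for T cell cytokines (0.8032), and blood 1 (0.8483) and lung 4 (0.8595) were lowest in their sites for transcription factors of effector and memory cells. Small intestine 4 was lowest for cytokine receptors (0.7283). Probes without a gene name, which the gene comparisons did not use, also passed the threshold: 3 of 2760 between lung and blood, 86 between small intestine and blood and 3 between lung and liver.

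The array labelled liver 5 held small intestinal genes and the array labelled small intestine 5 lacked them. The arrays were placed on 317 T cell list genes outside the marker lists, from 0 (mean of liver 1 to 4) to 1 (mean of small intestine 1 to 4). Small intestine 5 lay at 0.1167, among liver arrays 1 to 4 (0.0196 to 0.149). Intestinal cells carried into liver 5 would leave small intestine 5 where it was. The position may, however, follow the share of T cells as well as the site. Small intestine 1, 2 and 4 lay at 0.902, 1.26 and 0.857, with CD8 T cell identity means of 4.40, 3.75 and 3.57. Small intestine 3 lay at 0.344 with 5.44, and small intestine 5 averaged 5.22. A small intestine 5 fraction with few other cells could therefore lie near liver without an exchange. Its position thus does not decide against intestinal cells carried into liver 5. Liver 5 lay at 0.7307, within small intestine 1 to 4 (0.344 to 1.26), although its identity mean was 5.23. Cells carried into liver 5 could move it this way too. An exchange of the 2 labels may account for both arrays, a hypothesis that neither the positions nor the labels can settle. The arrays kept their labels here, and a biological difference between animals was not tested.

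Alveolar macrophage genes were higher in lung than in blood. Over the 5 lung arrays the markers kept nearly 1 ratio to each other: the median SD of a marker around the list mean was 0.2704 of the SD of the list mean. It was 0.329 without lung 3, where none of the markers was well above background. This is consistent with 1 cell type entering the sorted lung fraction in different amounts, although the cells had been sorted for the donor marker CD45.1. Chil3 lay between 6.37 and 8.21 on 4 lung arrays and at -2.13 on lung 3. Outside lung it lay at 3.32 on liver 4, 1.64 on small intestine 5 and 0.30 on blood 5. On the remaining arrays outside lung it lay between -3.70 and -1.37. Against blood neither the lung epithelium nor the endothelial list passed camera with an estimated correlation, though against liver both did. The lung epithelium markers Sftpc, Sftpd and Sftpa1 and the endothelial marker Flt1 were higher in lung too. If these genes are taken as markers, 1 cell type would not account for them all. Expression of these genes by the T cells themselves was not tested.

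Genes lower in small intestine than in blood were also set against the scaling of the arrays. Scaled on the probes well above background on all 20 arrays, the 799 genes had a median of -1.205 (SE 0.383) against -1.25 (SE 0.329), and 15 stayed past the threshold. The median residual SD was 0.606 against 0.520. With the first differences and the standard errors of the other scaling 19 would have passed, and with its differences and the first standard errors 577, so the larger spread ended most of the calls. All 799 genes still had an unadjusted p under 0.05 (limma) with the other scaling, so the lost calls missed only the adjusted threshold. The median of all genes moved alike, from -0.36 to -0.32, so this scaling tests too small a shift between the sites to decide, and scaling stays open as an explanation. A lower share of T cells in the sorted fraction could lower cell cycle and CD8 T cell identity genes alike. The difference of the list means was -2.21 ± 0.62 (SD, n = 5) in small intestine and -1.59 ± 0.49 in blood (exact two-sided permutation p = 0.1032), a gap of -0.62, so this explanation and a change within the T cells cannot be told apart with 5 arrays per site. A biological difference between the sites stays open.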

How the results depend on the processing

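Normexp on median signals, scaling on probes well above background on all 20 arrays, inclusion of unnamed probes and all omissions of 2 arrays were chosen after seeing the data. Normexp on mean signals, which was planned, was not run, and median signals took their place. The cause of a moved count was not tested, except for genes lower in small intestine than in blood under the other scaling. In the order liver, lung and small intestine against blood, lung and small intestine against liver, and small intestine against lung, the main counts were 0, 66, 873, 23, 0 and 12, with 61 in the F-test and 10 set apart in lung. Keeping non-uniform spots and including unnamed probes left each count within 1.5 times.

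Counts of lung against blood were 31 with quantile normalization, 34 with median scaling, 26 with the deposited value table, 24 with scaling on probes well above background on all arrays, 23 with only the 2 sites and 0 with only probes well above background on all arrays. Counts of genes differing between small intestine and blood were 510, 497, 495, 19 and 327 in the first 5 of these, and 254 with no filter. Counts of lung against liver were 13 with median scaling, and 0 with normexp, only the 2 sites or only probes well above background on all arrays. Counts of small intestine against lung were 28 with quantile normalization, 27 with the value table, 20 with scaling on probes well above background on all arrays, 7 with the mean of probes, 7 with a trended robust variance, and 0 with normexp, only the 2 sites or only probes well above background on all arrays. The F-test gave 8 with normexp, 24 with median scaling, 4 with only probes well above background on all arrays and 21 with scaling on them. Genes set apart in lung numbered 0 with normexp, 0 with only probes well above background on all arrays, 0 with only the 2 sites and 5 with the mean of probes. With no filter, 2 genes differed between liver and blood, 1 was set apart in blood and 1 was lower in all 3 organs.

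Without liver 5 and small intestine 5 the counts were 175 for lung against blood, 2119 for genes differing between small intestine and blood, 1312 for genes differing between small intestine and liver, 212 for genes differing between small intestine and lung, 1513 for genes differing among the 4 sites and 30 set apart in small intestine. With scaling on probes well above background on all arrays as well they were 531 (genes differing between lung and blood), 1919, 869, 111, 1466 and 26, with 5 between lung and liver and 4 set apart in lung. Without lung 4 and small intestine 4 they were 22 and 475 against blood, 9 between lung and liver, 5 between small intestine and lung, 25 in the F-test and 3 in lung.

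The replicate number as a block, which is also the slide, gave 3 genes between liver and blood, 114 between lung and blood and 2 higher in all 3 organs, and changed no other count by over 1.5 times. Same-numbered arrays deviated together in 18 of 30 pairs (correlation over 0.1, range -0.374 to 0.562), and 7 of 20 arrays correlated best with their own number in another site. No chance value was set for these counts, so they do not decide whether the numbers pair the arrays. The main fit left the block out because no label says what the number marks, although it is also the slide. With the site in the model 9 genes differed among slides.

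Leaving out 1 array gave 0 to 2, 16 to 846, 0 to 2037, 10 to 65, 0 to 822 and 3 to 118 genes in the 6 comparisons. It gave 13 to 1065 in the F-test, and 3 to 32 genes set apart in lung, 0 to 20 in small intestine, 0 to 1 in blood and 0 in liver. Genes higher in all 3 organs numbered 0, and genes lower in all 3 numbered 0 to 1. Of 83 calls of named genes, 33 stayed past the threshold with scaling on probes well above background on all arrays, 80 with the block and 79 without the 2 arrays, and over single arrays left out 499 stayed and 331 did not. Of 75 list calls, 4 held with an estimated correlation, 19 with fry and 75 with the block. No direction was reversed. Between 22.6% and 38.7% of probes stood well above background, which limits what dim genes can show.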

Other observations

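Of the tests of other splits, those within slides were chosen only after the result was seen. Of 38 gene lists tested with camera, 5, 13, 19, 8, 16 and 14 were called in the 6 comparisons, in the order liver, lung and small intestine against blood, lung and small intestine against liver, and small intestine against lung. With an estimated correlation 1, 0, 0, 3, 0 and 0 of these calls were kept, so most rest on the preset value. Some of the lists called were not described above. In lung against blood, hepatocyte markers had a median difference of 3.50 with 1 of 5 genes higher, dendritic cell markers 1.24 and markers of gamma delta and unconventional T cells 1.57 (camera adjusted p = 0.0254, 0.00327 and 0.0254, each 0.183 with an estimated correlation). Only 5 of 26 hepatocyte markers were measured, and the 1 called was Fabp1, also in the small intestinal epithelium list. The 5 averaged 1.29 ± 1.26 (SD, n = 5) in lung and -0.21 ± 0.61 in liver. In small intestine against blood, chemokines made by T cells had a median of 1.08 with 1 of 6 genes higher, and fibroblast and smooth muscle markers 1.30 (camera adjusted p = 0.0162 and 0.0227, both 0.203 with an estimated correlation). The 1 chemokine gene was Cxcl10, whose source cell was not determined. In small intestine against liver, adhesion and homing molecules had a median of -0.84, and 7 of 14 were lower when adjusted over the list alone (camera adjusted p = 0.0232, 0.370 with an estimated correlation). In the same comparison oxidative phosphorylation genes had a median of -0.41 over 39 genes (camera adjusted p = 0.0221, 0.678 with an estimated correlation).

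Fos lay at -2.98, -3.71 and -2.16 on blood arrays 3, 4 and 5. Mki67 lay between 5.01 and 5.79 on the liver, lung and blood arrays of slides 1 and 2, and between 1.14 and 4.23 on those of slides 3, 4 and 5. In small intestine it lay between 1.84 and 4.81.

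Other splits of the arrays into groups of the same sizes, 100 per result with the real one, were fitted with the slides ignored. All splits here, also those within slides, used the genes kept by the filter on the real sites. This favours the real split where genes passed through 1 site, so a low share does not exclude chance. For lung against blood 1 split gave as many genes (66, highest other 34). The same held for genes set apart in lung (1 split, 10 genes, highest other 0). For small intestine against blood 3 splits gave as many (873, highest other 1840), for lung against liver 3 (23, highest other 1369) and in the F-test 4 (61, highest other 2821), which is under 5 in 100 when the slides are ignored. The split with 1840 genes differed from the sites only by exchanging blood 1 and small intestine 5. Splits with several times the real count, between lung and liver and in the F-test, point to a structure of the samples; the one with 1369 genes exchanged liver 5 and lung 1. Chance cannot be excluded for small intestine against lung, where 12 splits gave at least 12 genes (highest other 1155). The result was 0 and 100 of 100 splits gave as many for liver against blood (highest other 26), small intestine against liver (highest other 1512), genes set apart in liver (highest other 0), small intestine (highest other 1) or blood (highest other 0), and genes higher or lower in all 3 organs (highest other 0 for both). Splits that keep 1 array of each site on every slide number 16 for 2 sites, too few for a share under 0.05. The real count was the highest for lung against blood (66, highest other 0), small intestine against blood (873, highest other 14), lung against liver (23, highest other 11) and small intestine against lung (12, highest other 3). Over the 4 sites, 2 of 100 such splits gave as many genes in the F-test (61, highest other 371) and 1 of 100 as many set apart in lung (10, highest other 0). In the split with 1512 genes, liver 1 to 4 with small intestine 5 stood against small intestine 1 to 4 with liver 5.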
